A study of Mus musculus with 12 samples.

How the data were processed

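RNA was measured by sequencing in interscapular brown adipose tissue of 12-week-old C57BL/6 mice, taken at zeitgeber time 9. Per the labels, each of the 12 libraries was made from RNA of 2 mice of 1 genotype and 1 condition, 250 ng from each, so that a pool of 500 ng was sequenced. There were 4 groups of 3 pools: control littermates and mice with a Cdk7 deletion directed to brown fat, each at room temperature and 6 h into a cold exposure with food present. Groups were taken from the labels alone. The sex of the mice, the temperature of the cold, the driver of the deletion, the library kit and the sequencing dates were not given in the sources used here, so no batch could be set against the groups.

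The deposited values were raw counts of reads per Ensembl gene, 1 file per pool, not normalised. Per the submitters' processing notes, the authors aligned reads with STAR and counted them with HTSeq on genome build GRCm38, and versions were not given. The names of the deposited files refer to a reverse strand setting of the counting, but the library kit and the setting are not given elsewhere in the sources used here. Genes that overlap another annotated gene on either strand are therefore reported as uncertain. Each file held 53379 gene IDs and 5 summary lines of HTSeq. The summary lines were left out of library sizes and tests. Relative to all lines of a file they held 1.64 to 2.26% for reads outside genes, 1.07 to 1.37% for ambiguous reads, 1.12 to 1.86% for unaligned reads and 26.6 to 30.2% for reads with several alignments. Reads with several alignments were in no gene, so near-identical copies such as Hspa1a and Hspa1b are undercounted, and their values rest on reads that the aligner placed once. Gene names and GRCm38 coordinates came from a matching annotation, which held 53274 of the 53379 IDs.

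The gene counts summed per library ran from 27609717 to 36792555. In R 4.3.3, edgeR 4.0.16 was run on the counts as deposited: genes were filtered with filterByExpr by group, which left 15208 genes and took out 38171, libraries were scaled by TMM factors (0.798 to 1.18), and a negative binomial model with 1 mean per group was fitted to all 12 libraries with robust estimates. The common biological coefficient of variation was 13.6%. Adjusted p of single genes come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 15208 genes, except those given for an alternative, which come from its own tool and its own number of genes, and 0.05 was the threshold. Where adjusted p is given as a range over alternatives, its low end can lie far below the main value and is not read as support. The standard error of a log2 fold change was the fold change divided by the square root of the F statistic. Fitted log2 fold changes used a prior count of 0.125. Levels are given as CPM, the counts scaled to a common library size, normalised by the TMM factors.

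The 4 pairwise comparisons and the difference between both cold responses (the interaction of genotype and cold) were fixed with their tests, the gene lists, the rule for named genes and most of the alternative settings before the data were examined. There were 23 lists of programmes and 9 lists of cell type markers. Of these, 31 had at least 5 tested members and were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, 2-sided, with adjustment over the 31 lists, then again with the correlation estimated per list, and with fry. Camera asks whether a list moved relative to all other genes. Fry asks whether its members moved on balance in 1 direction, without reference to other genes. Where a list is said to pass or not, camera is meant unless fry is named. By fry 20 lists passed for KO against WT at room temperature and 24 in the cold. For cold in WT 12 passed by fry, for cold in KO 8 and for the difference between both cold responses 5. The named genes were Cdk7, Ucp1, Ppargc1a and Dio2 whatever their result, and, per pairwise comparison, the 10 largest rises and 10 largest falls among genes past the test with a mean log2 CPM of at least 1, groups that did not overlap and an official symbol. For the difference between both cold responses the rule took 5 in each direction, without the condition on overlap. From each list described it took up to 4 members with the smallest p. Fewer are named here than the rule allows, with preference for those whose call held under the alternatives. Some genes that the rule takes are not reported here.

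The alternatives tried were median-ratio size factors, no filter beyond 1 count, a strict filter (CPM of at least 1 in 6 libraries), the Wald test of DESeq2 1.42.0, limma voom with sample weights, only the 6 libraries compared, mitochondrially encoded genes left out, the replicate number as a block and each library left out in turn. Added after the data had been seen were library totals alone without TMM factors, the skeletal muscle list as a covariate and a fit without the 2 libraries richest in skeletal muscle transcripts. The tests were first run on counts simulated for the comparison of genotypes at room temperature over 15208 genes, with 50 genes changed per fold size. For edgeR, 1 of 50 genes changed 1.25-fold, 26 of 50 changed 1.5-fold, 39 of 50 changed 2-fold and 50 of 50 changed 4-fold were recovered, with 8 false calls. With 1 list of 11 members shifted by 0.5 on the log2 scale, camera recovered it and called 0 of 30 others. The simulated genes were drawn independently of each other. In the data the correlation estimated for KO against WT at room temperature was 0.3 for the heat shock list and 0.42 for the respiratory chain list. The simulation therefore does not show how often camera at the preset correlation calls such lists falsely. Pools are the replicates, so p-values measure the spread between pools of 2 mice and not between single animals.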

Results

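Transcript levels were measured in interscapular brown fat, the tissue that burns lipid for heat, of mice in which Cdk7 was deleted in brown fat (KO) and of control littermates (WT). Cdk7 is the catalytic subunit of the CDK-activating kinase and a part of the general transcription factor TFIIH. Each genotype was sampled at room temperature and 6 h into a cold exposure, with 3 pools of 2 mice in each of the 4 groups. Assigned reads per library ran from 27609717 in WT cold replicate 2 to 36792555 in WT room temperature replicate 3. Between 13149 and 15052 genes had at least 10 counts, and the 10 most abundant genes took 35.1 to 47.6% of the counts. Mitochondrially encoded transcripts made up 31.1 to 42.5% of each library. The Y-linked gene Ddx3y had 2155 to 3923 counts in every library, and Xist had 0 to 6. Correlations of log2 CPM between libraries were 0.976 to 0.991 within groups and 0.942 to 0.982 between groups, across genes, which are not independent replicates. Counts of libraries within a group differed by more than sampling noise, with chi-square values of 11.4 to 99 per degree of freedom. The first 3 principal components of the 500 most variable genes held 39.2, 36 and 13.8% of the variance. All 15 skeletal muscle markers were among those genes, and the second component followed their log2 level over the 12 libraries (Pearson's r = 0.852, permutation p = 0.00047, adjusted 0.0014 over 3 components, and Spearman's rho = 0.832, permutation p = 0.0014, adjusted 0.0043). Without the 2 libraries farthest from the median level, r was 0.809. The markers were among the genes that made the component, so part of this relation is built in, and the permutation does not take that into account. Throughout, the value after ± is the standard error for a log2 fold change and the SD for CPM, each with n = 3 pools per group, and positions are on GRCm38. Among the genes named for the size of their change, Car14 overlaps Aph1a on the opposite strand, Acsm3 overlaps Eri2, B3galt2 overlaps Cdc73 and Srebf1 overlaps Rai1, so their values are uncertain. The same holds, with predicted or small RNA genes as partners, for Zdbf2, Slc16a12, Eci3, P2ry1, Cfap53, Gsta3, St3gal5, Tectb, Hspa1a, B4galnt2, Angpt1, Ano1, Kcne4, Atf3, Tuba8, Ucp3 and Lclat1.

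Skeletal muscle transcripts varied between libraries of the same group. The summed level of the 15 skeletal muscle markers was 273, 832 and 27.9 CPM in the WT pools at room temperature and 25.2, 15.5 and 1272 CPM in the KO pools at room temperature. In the cold it was 89.4, 9.5 and 9.8 CPM in WT and 33.4, 177 and 263 CPM in KO. The median log2 fold change of these markers was -0.01 for KO against WT at room temperature, 1.71 for KO against WT in the cold, -3.23 for cold in WT and -1.36 for cold in KO. The list did not pass in any of these comparisons (adjusted p = 0.54, 0.28, 0.28 and 0.87). The libraries richest in these transcripts were KO room temperature replicate 6 and WT room temperature replicate 2.

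Cdk7 (ENSMUSG00000069089, chromosome 13, 100702631 to 100730939, minus strand) was measured first, as the deleted gene. The WT pools at room temperature had 16.4, 15.1 and 16.1 CPM and the KO pools 4.35, 5.15 and 5.77 CPM. In the cold the WT pools had 17.9, 16.1 and 15.7 CPM and the KO pools 5.38, 4.85 and 5.39 CPM. Every KO pool was below every WT pool, and the mean level in KO was 32% of WT at room temperature (log2 fold change -1.64 ± 0.12, adjusted p = 3.8e-08) and 31.4% in the cold (-1.67 ± 0.12, adjusted p = 2e-08). The tissue also holds cells other than brown adipocytes, and gene counts do not show which exons the remaining reads cover. Cold gave Cdk7 values of 0.06 ± 0.11 in WT (adjusted p = 0.67) and 0.04 ± 0.12 in KO (adjusted p = 0.87). Of the 10 tested members of the TFIIH and CDK-activating kinase list, 1 was higher and 3 were lower in KO at room temperature over all genes tested, and 2 and 5 adjusted over the list alone. Besides Cdk7, Ccnh, the cyclin partner of Cdk7, was lower at room temperature (-0.32 ± 0.09) and in the cold (-0.53 ± 0.09). The list as a whole did not pass with camera (median -0.13 at both temperatures, adjusted p = 0.16 and 0.083). By fry it passed at room temperature (adjusted p = 3.7e-05) and in the cold (adjusted p = 3.5e-06), with the deleted gene Cdk7 among its members.

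**Figure D1:**
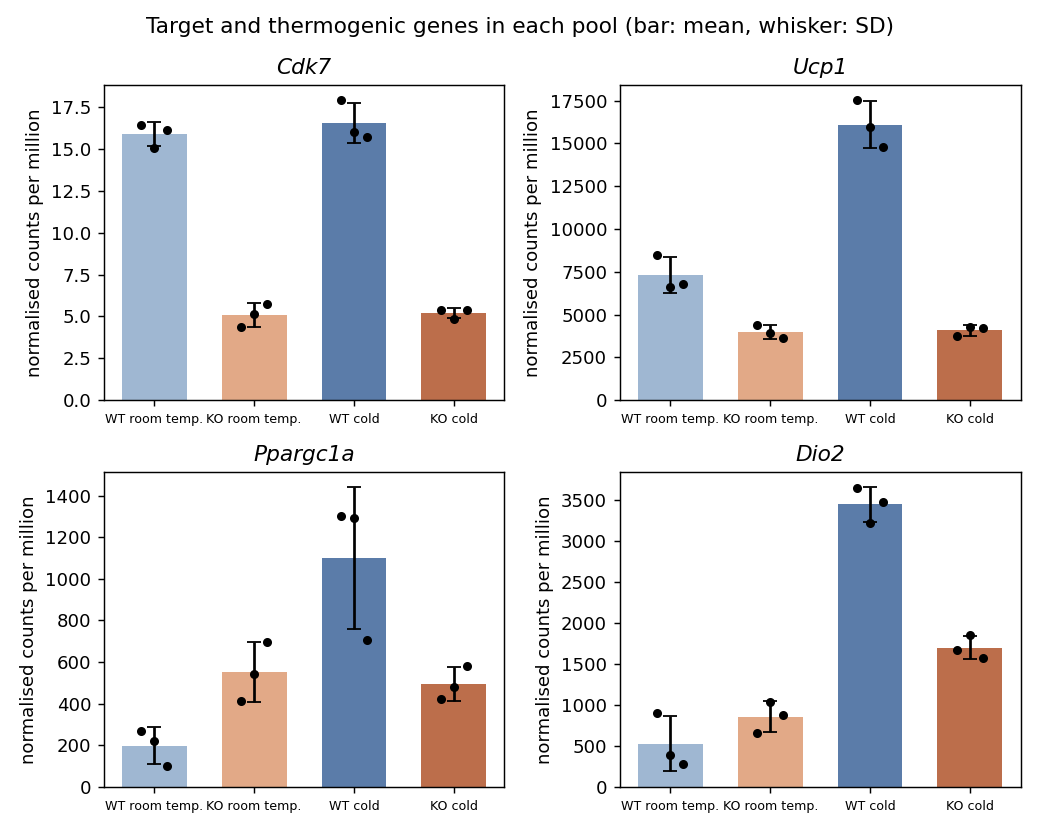
Normalised CPM of Cdk7, Ucp1, Ppargc1a and Dio2 in the 4 groups, with bars for the group mean, whiskers for the SD and points for each of the 3 pools per group. Mean Cdk7 was 5.09 CPM in KO against 15.9 CPM in WT at room temperature, and mean Ucp1 reached 16100 CPM in WT in the cold against 4070 CPM in KO.

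The comparison of KO with WT at room temperature asks what loss of Cdk7 changes in brown fat without a cold challenge. Ucp1, which uncouples respiration to make heat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452, plus strand), fell 1.84-fold from 7310 ± 1040 to 3970 ± 397 CPM (log2 fold change -0.88 ± 0.12, adjusted p = 3.4e-05). Car6, a secreted carbonic anhydrase (chromosome 4, 150187015 to 150201332, minus strand), rose 87.5-fold from 0.134 ± 0.0198 to 12 ± 0.694 CPM (6.45 ± 0.26). Lgals3, the macrophage lectin galectin-3, rose 7.59-fold from 2.98 ± 0.465 to 22.8 ± 4.12 CPM. Btc, a ligand of the EGF receptor, fell 7.92-fold from 6.09 ± 1.03 to 0.762 ± 0.18 CPM. Further rises by over 8-fold were measured for Otof, a calcium-binding protein of membrane fusion (3.68 ± 0.2), Gpnmb, a glycoprotein of macrophages (3.61 ± 0.77, or 2.79 without KO room temperature replicate 6 and 2.86 without the libraries richest in skeletal muscle transcripts), Slc16a12, a creatine transporter (3.07 ± 0.22), Pimreg (3.41 ± 0.22) and Zdbf2 (3.09 ± 0.32). Among the falls were Mmd2 (-3.15 ± 0.33), the carbonic anhydrase Car14 (-2.63 ± 0.48, or -3.5 without KO room temperature replicate 4), the acyl-CoA synthetase Acsm3 (-2.35 ± 0.19), the enoyl-CoA isomerase Eci3 (-2.37 ± 0.25) and the purinergic receptor P2ry1 (-2.3 ± 0.29).

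Genes of lipid burning were lower in KO at room temperature. In the fatty acid uptake and oxidation list 14 of 19 genes fell and 0 rose, also 14 and 0 adjusted over the list alone, among them Etfdh (-0.73 ± 0.08), Slc25a20, the mitochondrial carnitine carrier (-0.72 ± 0.09), and the thiolase Acaa2 (-0.68 ± 0.1). The fatty acid oxidation median was -0.38 (adjusted p = 2.3e-05, and adjusted p = 0.11 with an estimated correlation). In the nuclear-encoded respiratory chain list 18 of 23 genes fell and 0 rose, or 19 and 0 adjusted over the list alone, including Sdhb of complex II (-0.55 ± 0.09) and Ndufa4 (-0.64 ± 0.12). The respiratory chain median was -0.4 (adjusted p = 9.5e-06, and adjusted p = 0.26 with an estimated correlation). Of 17 thermogenic genes 8 fell and 1 rose, the same counts adjusted over the list alone, with falls of the nuclear receptors Esrrg (-0.99 ± 0.08) and Ppara (-1.43 ± 0.14) and of Ebf2, a transcription factor of brown adipocytes (-0.83 ± 0.1). The thermogenic median was -0.24 (adjusted p = 0.0064, and adjusted p = 0.13 with an estimated correlation). The member that rose was Ppargc1a, a coactivator of mitochondrial genes (ENSMUSG00000029167, chromosome 5, 51454250 to 51567726, minus strand, overlapping predicted genes), from 198 ± 88 to 552 ± 143 CPM (1.48 ± 0.4, adjusted p = 0.018). Its call ended without KO room temperature replicate 6 (1.27, adjusted p = 0.061), in a fit of the 6 libraries compared (1.49, adjusted p = 0.065) and without the libraries richest in skeletal muscle transcripts (1.37, adjusted p = 0.11), and over its alternatives adjusted p ran from 3.7e-37 to 0.11. Dio2, which activates thyroid hormone (ENSMUSG00000007682, chromosome 12, 90724552 to 90738438, minus strand, with an antisense gene), had 524 ± 334 CPM in WT and 853 ± 189 CPM in KO and did not pass (0.7 ± 0.38, adjusted p = 0.18). Without WT room temperature replicate 1 it was higher in KO (1.35, adjusted p = 3.8e-05), without WT room temperature replicate 3 its value was 0.4, it also passed with no filter beyond 1 count, library totals alone and limma voom, and over its alternatives adjusted p ran from 7.8e-08 to 0.51. Among general adipocyte genes 8 of 14 fell and 0 rose, likewise adjusted over the list alone, with Zfp423 at -0.91 ± 0.1 and the lipid droplet coat gene Plin1 at -0.68 ± 0.09. Their list median was -0.34 (adjusted p = 0.0012, and adjusted p = 0.11 with an estimated correlation).

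Markers of immune and stromal cells were higher in KO at room temperature. Of 13 macrophage genes 11 rose and 0 fell, or 11 and 1 adjusted over the list alone, including the complement genes C1qa (1.38 ± 0.1), C1qb (1.55 ± 0.1) and C1qc (1.43 ± 0.13) and the lysosomal marker Cd68 (2.07 ± 0.23). The macrophage median was 1.43 (adjusted p = 6.1e-11, and adjusted p = 0.11 with an estimated correlation). Extracellular matrix genes rose in 13 of 17 cases and fell in 1, or 14 and 1 adjusted over the list alone, with Mmp2 at 0.95 ± 0.1, the basement membrane collagen Col4a1 at 0.87 ± 0.12 and Postn at 0.81 ± 0.12. For the matrix list the median was 0.58 (adjusted p = 8.7e-06, and adjusted p = 0.11 with an estimated correlation). Endothelial markers rose in 8 of 11 cases, or 9 adjusted over the list alone, with Pecam1 at 0.78 ± 0.1. For endothelium the median was 0.39 (adjusted p = 0.0022, and adjusted p = 0.16 with an estimated correlation). Smooth muscle and pericyte markers rose in 7 of 10 cases and fell in 2, or 8 and 2 adjusted over the list alone, with Tagln at 1.29 ± 0.11 and Acta2 at 1.43 ± 0.19. For smooth muscle and pericytes the median was 0.44 (adjusted p = 0.0033, and adjusted p = 0.16 with an estimated correlation). Of 11 heat shock genes 8 rose and 1 fell, with the same counts adjusted over the list alone, among them the chaperones Hspb1 (1.15 ± 0.1), Hsph1 (1.65 ± 0.19) and Dnajb1 (1.27 ± 0.17). The heat shock median was 0.92 (adjusted p = 0.00011, and adjusted p = 0.16 with an estimated correlation). Of 15 p53 targets 5 rose and 0 fell, also adjusted over the list alone, with the apoptosis gene Bax at 1.04 ± 0.12 and the nuclease Aen at 0.73 ± 0.09. For p53 targets the median was 0.21 (adjusted p = 0.014, and adjusted p = 0.11 with an estimated correlation).

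In all, 2940 genes were higher and 3198 lower in KO at room temperature, 969 and 561 of them by over 2-fold, among 15208 tested. Of 31 lists, 15 passed at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.11). Groups of pools did not overlap for 48.8% of genes, where chance gives 10%. With library totals alone the median of all genes went from 0 to 0.22 and the split was 4739 higher and 1267 lower. The macrophage median was then 1.63, while 0 members of the fatty acid oxidation list rose and 5 fell (median -0.16), 0 respiratory chain genes rose and 2 fell (-0.19), 2 thermogenic genes rose and 5 fell (-0.06), and 1 adipocyte gene rose and 4 fell (-0.13). That scaling put Sdhb at -0.34, endothelial markers at a median of 0.61 and p53 targets at 0.43. Without the libraries richest in skeletal muscle transcripts 3566 genes changed.

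The comparison of KO with WT in the cold asks which differences are present when brown fat is challenged to make heat. Ucp1 was 3.95-fold lower in KO, at 4070 ± 304 against 16100 ± 1380 CPM (log2 fold change -1.98 ± 0.13, adjusted p = 6.9e-09). Lgr6, a receptor for R-spondins (chromosome 1, 134983301 to 135105276, minus strand), was 21.2-fold lower, at 10.9 ± 3.26 against 230 ± 35.4 CPM (-4.4 ± 0.21, adjusted p = 5.4e-08). Fabp3, a fatty acid binding protein (chromosome 4, 130308595 to 130315463, plus strand, antisense to Zcchc17 and therefore uncertain), was 13.9-fold lower, at 44 ± 19.1 against 611 ± 138 CPM. Car6 was again higher, at 15.7 ± 3.66 against 0.2 ± 0.0777 CPM (6.27 ± 0.25). Larger values in KO were also found for Cfap53, a ciliary gene (4.61 ± 0.28), Slc16a12 (3.93 ± 0.24), Otof (3.54 ± 0.21), the glutathione transferase Gsta3 (2.98 ± 0.47, or 3.57 without WT cold replicate 3) and Itgax, an integrin of dendritic cells and macrophages (2.93 ± 0.6). Lower in KO were St3gal5, which makes the ganglioside GM3 (-3.27 ± 0.29), Slc25a34 of the mitochondrial carrier family (-3.07 ± 0.39), the transcription factor E2f2 (-2.88 ± 0.34) and Tectb (-2.92 ± 0.25).

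In the thermogenic list 12 of 17 genes were lower in KO in the cold and 0 higher, or 13 and 0 adjusted over the list alone, including Esrrg (-1.29 ± 0.09), Esrra (-1.1 ± 0.09) and Ebf2 (-1.1 ± 0.1). The list median was -1.14 (adjusted p = 2.9e-08), and the call held with an estimated correlation (adjusted p = 0.03). Ppargc1a was lower in KO, at 494 ± 81.3 against 1100 ± 342 CPM (-1.16 ± 0.4, adjusted p = 0.036), but this call ended without WT cold replicate 1 or 2 (-1.02 each, adjusted p = 0.1), KO cold replicate 1 (-1.05, adjusted p = 0.11), KO cold replicate 2 (-1.14, adjusted p = 0.092) or KO cold replicate 3 (-1.29, adjusted p = 0.057) and with library totals alone (-0.72, adjusted p = 0.11). With the replicate number as a block the call of Ppargc1a ended too. Its adjusted p over all alternatives ran from 5.3e-23 to 0.11. Dio2 had 1700 ± 139 CPM in KO and 3440 ± 215 in WT and did not pass (-1.02 ± 0.39, adjusted p = 0.052), with adjusted p from 3.5e-16 to 0.15 over its alternatives. It passed with no filter beyond 1 count, in a fit of the 6 libraries compared, with DESeq2 and with limma voom. The lipolysis and lipid droplet list had 8 of 15 genes lower and 1 higher, also adjusted over the list alone, with Plin5 at -1.28 ± 0.1, Plin1 at -1.07 ± 0.09 and the beta-1 adrenergic receptor Adrb1 at -1.66 ± 0.16. The lipolysis median was -0.48 (adjusted p = 6e-04, and adjusted p = 0.18 with an estimated correlation). Lower values also came from genes of fatty acid uptake, such as Lpl (-1.03 ± 0.12) and Acsl1 (-1.18 ± 0.14), and of glycolysis, such as Pfkfb3 (-1.5 ± 0.12) and Pfkp (-0.83 ± 0.1). Of 19 genes of fatty acid uptake and oxidation 13 were lower and 2 higher (adjusted p = 0.0015, and adjusted p = 0.18 with an estimated correlation). Of 17 glycolysis genes 10 were lower and 0 higher (adjusted p = 0.0019, and adjusted p = 0.18 with an estimated correlation). Both list medians turned positive with library totals alone. Of 20 lipogenesis genes 12 were higher and 4 lower, also adjusted over the list alone, with malic enzyme Me1 at 1.43 ± 0.21 and Gpam at -1.92 ± 0.11. As a list, lipogenesis had a median of 0.58 (adjusted p = 0.026, and adjusted p = 0.39 with an estimated correlation). That call ended without WT cold replicate 1 (0.53, adjusted p = 0.063).

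Macrophage markers were again higher in 11 of 13 cases, also adjusted over the list alone, with C1qb at 1.27 ± 0.1 and the lipid receptor Trem2 at 3.67 ± 0.47. The macrophage list had a median of 1.59 (adjusted p = 7e-09, and adjusted p = 0.15 with an estimated correlation). Of 19 cell cycle genes 14 were higher and 0 lower, or 15 and 0 adjusted over the list alone, among them Top2a (2.23 ± 0.25) and Mki67 (1.48 ± 0.21). The cell cycle median was 1.05 (adjusted p = 6e-04, and adjusted p = 0.18 with an estimated correlation). Of 16 interferon response genes 12 were higher and 0 lower, also adjusted over the list alone, with Irf7 at 1.21 ± 0.16 and Ifit2 at 1.13 ± 0.16. The interferon median was 0.84 (adjusted p = 6e-04, and adjusted p = 0.26 with an estimated correlation). Of 15 p53 targets 9 were higher and 0 lower, also adjusted over the list alone, with Trp53inp1 at 1.35 ± 0.13. The p53 median was 0.64 (adjusted p = 0.0011, and adjusted p = 0.064 with an estimated correlation). Heat shock genes split, with 3 of 11 higher and 5 lower, also adjusted over the list alone, the lower ones led by the constitutive chaperones Hspa8 (-1.78 ± 0.1) and Hsp90ab1 (-1.56 ± 0.1). Their median was -0.18 (adjusted p = 0.0062, and adjusted p = 0.27 with an estimated correlation), or -0.1 without WT cold replicate 1 and -0.27 without WT cold replicate 3, and it turned to 0.26 with library totals alone. Of the 9 tested mitochondrially encoded genes 8 were lower, also adjusted over the list alone, with mt-Nd5 at -1.26 ± 0.24. The median of these genes was -0.77 (adjusted p = 0.03, and adjusted p = 0.4 with an estimated correlation), and 2 of the 9 had fewer than 100 counts in every library. This call also ended with the replicate number as a block.

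In the cold 3939 genes were higher and 4222 lower in KO, 1611 and 659 of them by over 2-fold, and groups did not overlap for 62.7% of genes against 10% by chance. Of the lists, 19 passed at the preset correlation and 1 with an estimated one. Scaling by library totals alone moved the median of all genes from 0.01 to 0.45 and the split was then 7881 higher and 1073 lower. The thermogenic median stayed negative with that scaling (-0.68, with 9 genes lower and 2 higher), as did Esrrg (-0.85), Esrra (-0.66), Ebf2 (-0.66), Plin1 (-0.63), Plin5 (-0.84), Lpl (-0.59), Acsl1 (-0.75), Pfkp (-0.39) and mt-Nd5 (-0.82). Medians turned from -0.37 to 0.07 for fatty acid uptake and oxidation, from -0.27 to 0.17 for the respiratory chain, from -0.29 to 0.15 for glycolysis and from -0.36 to 0.07 for general adipocyte genes, so no direction is given for these lists. With that scaling 4 lipolysis genes were higher and 5 lower (median -0.04), and 1 mitochondrially encoded gene was higher and 3 lower (-0.33). The median was then 1.01 for lipogenesis, 1.08 for p53 targets and 1.28 for interferon response genes.

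The comparison of cold with room temperature in WT asks what 6 h of cold changes in brown fat of control mice. Ucp1 rose 2.2-fold (log2 fold change 1.14 ± 0.12, adjusted p = 1.5e-06), Ppargc1a rose from 198 ± 88 to 1100 ± 342 CPM (2.48 ± 0.41, adjusted p = 0.0013) and Dio2 from 524 ± 334 to 3440 ± 215 CPM (2.72 ± 0.41, adjusted p = 0.00066, or 3.37 without WT room temperature replicate 1). Hspa8, an abundant chaperone (chromosome 9, 40800984 to 40810087, plus strand), rose 8.53-fold from 530 ± 31 to 4520 ± 442 CPM (3.09 ± 0.11, adjusted p = 7.3e-12). Hcar1, the lactate receptor of adipocytes, fell 15-fold from 31.8 ± 2.4 to 2.11 ± 1.08 CPM (-3.9 ± 0.29), and the angiopoietin Angpt1 fell from 23.4 ± 5.01 to 1.83 ± 0.318 CPM (-3.67 ± 0.27). Dgkg, a diacylglycerol kinase (chromosome 16, 22468461 to 22657221, minus strand, overlapping other genes and therefore uncertain), rose 46.5-fold to 13.6 ± 1.48 CPM. Rises were also measured for the acyl-CoA thioesterase Acot5 (4.93 ± 0.6, or 6.55 without WT room temperature replicate 1 and 6.12 with limma voom), hemopexin Hpx (4.43 ± 0.28), B4galnt2 (3.94 ± 0.31), Pimreg (3.93 ± 0.22) and the chaperone Hsph1 (3.64 ± 0.2). Falls were measured for the receptor kinase Kit (-3.79 ± 0.76), Btc (-2.97 ± 0.25), the chloride channel Ano1 (-2.85 ± 0.16), the niacin and ketone body receptor Hcar2 (-2.7 ± 0.45), Sntb1 (-2.84 ± 0.13) and B3galt2 (-2.77 ± 0.24).

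Every one of the 11 heat shock genes rose in WT in the cold, also adjusted over the list alone, with Hsp90aa1 at 2.62 ± 0.16, Hsp90ab1 at 1.93 ± 0.1 and Hspb1 at 1.9 ± 0.11. The inducible Hsp70 genes Hspa1a (5.29 ± 0.4) and Hspa1b (5.3 ± 0.53) are near-identical, so reads that align to both were left out and both are undercounted. The heat shock median was 2.18 (adjusted p = 3.4e-34), 1.99 with library totals alone, and the call held with an estimated correlation (adjusted p = 0.01). Lipogenesis genes fell in 12 of 20 cases and rose in 2, or 13 and 2 adjusted over the list alone, with falls of Dgat2, which forms triglyceride (-2 ± 0.16), Aacs (-2.56 ± 0.34) and Acss2 (-0.86 ± 0.15), and a rise of Gpam (0.93 ± 0.11). The lipogenesis median was -0.55 (adjusted p = 0.0043, and adjusted p = 0.62 with an estimated correlation). Of 13 genes for other transcriptional kinases and RNA polymerase II factors 9 rose and 1 fell, also adjusted over the list alone, with the elongation factor Supt5 at 1.46 ± 0.1, the Mediator kinase Cdk8 at 0.63 ± 0.08 and its paralog Cdk19 at -0.9 ± 0.1. The median of this list was 0.39 (adjusted p = 0.0043, and adjusted p = 0.62 with an estimated correlation). Glycolysis genes rose in 8 of 17 cases and fell in 1, or 9 and 1 adjusted over the list alone, including Pfkp (1.06 ± 0.1) and Hk1 (1.01 ± 0.11). The glycolysis median was 0.28 (adjusted p = 0.018, and adjusted p = 0.62 with an estimated correlation), or 0.07 with library totals alone. The thermogenic list had 9 of 17 genes higher and 4 lower, also adjusted over the list alone, with Kcnk3 at 1.02 ± 0.17 and Esrrg at -0.73 ± 0.08. It did not pass with camera (median 0.67, adjusted p = 0.091) but did with fry (adjusted p = 0.00086). Clock genes Arntl (2.43 ± 0.26) and Nr1d1 (1.28 ± 0.16) rose and Hlf fell (-1.71 ± 0.12). The circadian list did not pass with camera (median 0.59, adjusted p = 0.22) but did with fry (adjusted p = 0.0038).

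Cold in WT raised 3503 genes and lowered 3531, 651 and 1126 of them by over 2-fold, and groups did not overlap for 55.4% of genes against 10% by chance. Scaled by library totals alone, the median of all genes went from -0.03 to -0.23, the split was 1826 higher and 4813 lower, the transcriptional kinase median was 0.19 and the lipogenesis median -0.76. The mitochondrial ribosomal RNAs mt-Rnr1 (1.95 ± 0.17) and mt-Rnr2 (2.23 ± 0.23), named after their values were seen, were higher in the cold libraries, and each cold library exceeded each room temperature library in both. The library kit and the sequencing dates are not known, so cold cannot be told apart here from a separate preparation of the cold libraries. With mitochondrially encoded genes left out, 7032 genes changed. The number of lists past the test was 4, or 8 without WT room temperature replicate 1, 8 with library totals alone and 1 with an estimated correlation.

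The comparison of cold with room temperature in KO asks what cold changes in brown fat with the Cdk7 deletion. The inducible chaperone genes Hspa1a (log2 fold change 4.65 ± 0.32, from 1.91 to 48.1 ± 11.5 CPM) and Hspa1b (4.27 ± 0.44) rose, with the same undercount from their shared reads. Ttpa, the tocopherol transfer protein, rose 9.31-fold from 2.35 ± 0.408 to 21.8 ± 5.37 CPM (3.22 ± 0.19, adjusted p = 1.5e-07), and Cfap53 rose to 10.4 ± 1.61 CPM (2.67 ± 0.23). Lgr6 fell 4.07-fold, from 44.2 to 10.9 ± 3.26 CPM (-2.02 ± 0.2). Ucp1 had 3970 ± 397 CPM at room temperature and 4070 ± 304 CPM in the cold (0.04 ± 0.12, adjusted p = 0.88), Ppargc1a had 552 ± 143 and 494 ± 81.3 CPM (-0.16 ± 0.39, adjusted p = 0.84) and Dio2 had 853 ± 189 and 1700 ± 139 CPM (0.99 ± 0.39, adjusted p = 0.13, between 7e-16 and 0.3 over its alternatives, with calls from the fit without filter, the fit of the 6 libraries compared and limma voom). Rises were also measured for the potassium channel subunit Kcne4 (2.65 ± 0.41), the cytokine signalling inhibitor Socs2 (2.19 ± 0.35), the stress-induced transcription factor Atf3 (2.1 ± 0.38) and Tent5c (2.03 ± 0.32). Falls were measured for the incretin receptor Gipr (-1.59 ± 0.18), the uncoupling protein gene Ucp3 (-1.56 ± 0.26), the lipogenic transcription factor Srebf1 (-1.51 ± 0.27), Trarg1, which acts in glucose transporter trafficking (-1.59 ± 0.16), the tubulin gene Tuba8 (-1.59 ± 0.21) and B3galt2 (-1.41 ± 0.22).

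All 11 heat shock genes rose in KO too, also adjusted over the list alone, with Hspb1 at 0.94 ± 0.1, Hspa8 at 0.9 ± 0.1 and Hsph1 at 1.8 ± 0.19. The median was 0.94 (adjusted p = 3.2e-26), and the call held with an estimated correlation (adjusted p = 0.012). Of 20 lipogenesis genes 5 fell and 0 rose, also adjusted over the list alone, among them Dgat2 (-0.82 ± 0.16) and Mlxipl, the carbohydrate response factor (-1.07 ± 0.19). The lipogenesis median in KO was -0.32 (adjusted p = 0.00044, and adjusted p = 0.36 with an estimated correlation). Of 17 beta-adrenergic and immediate-early genes 5 rose and 0 fell, also adjusted over the list alone, with the cAMP-responsive gene Crem at 0.74 ± 0.14. The median over this list was 0.3 (adjusted p = 0.0094, and adjusted p = 0.85 with an estimated correlation). This call ended without KO cold replicate 3 (0.23, adjusted p = 0.13). Of 15 lipolysis and lipid droplet genes 6 fell and 1 rose, or 6 and 2 adjusted over the list alone, with hormone-sensitive lipase Lipe at -0.93 ± 0.11 and Hilpda, an inhibitor of lipolysis, at 1.08 ± 0.21. Over the lipolysis list the median was -0.23 (adjusted p = 0.0094, and adjusted p = 0.36 with an estimated correlation). This call ended without KO room temperature replicate 5 (-0.24, adjusted p = 0.065). The adipocyte transcription factor Cebpa fell (-1.09 ± 0.09), as did Esrrg (-1.02 ± 0.08) and Ebf2 (-0.82 ± 0.1). The thermogenic list had 1 gene higher and 4 lower of 17, also adjusted over the list alone. It did not pass with camera (median -0.14, adjusted p = 0.11) but did with fry (adjusted p = 0.034).

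Cold in KO raised 1109 genes and lowered 1149, 237 and 155 of them by over 2-fold, and groups did not overlap for 32.8% of genes against 10% by chance. The count of 2258 was 1328 without KO room temperature replicate 6, 1171 without KO cold replicate 1, 1274 without KO cold replicate 2, 1476 with library totals alone (801 higher and 675 lower), 1214 without the libraries richest in skeletal muscle transcripts and 4092 with limma voom. The median of all genes was 0 with library totals alone. As in WT and with the same limit, mt-Rnr1 (1.6 ± 0.17) and mt-Rnr2 (1.31 ± 0.22) were higher in the cold libraries, each of which exceeded each room temperature library. With mitochondrially encoded genes left out 2253 genes changed. The number of lists past the test was 9, or 5 without KO room temperature replicate 5 and 1 with an estimated correlation.

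Whether the cold response differs between genotypes was tested as an interaction. The rise of Ucp1 in the cold was smaller in KO (difference of log2 fold changes -1.1 ± 0.17, adjusted p = 0.00037), as were those of Hspa8 (-2.2 ± 0.14, adjusted p = 2.1e-07), Dgkg (-3.88 ± 0.4, adjusted p = 1.2e-05) and Pimreg (-3.51 ± 0.28, adjusted p = 1.3e-06). The fall of Angpt1 was smaller in KO (3.21 ± 0.36, adjusted p = 0.00014), as was that of Hcar1 (2.73 ± 0.38, adjusted p = 0.00083). Ppargc1a also differed (-2.64 ± 0.56, adjusted p = 0.011), with adjusted p from 3.2e-58 to 0.058 over its alternatives, the highest without the libraries richest in skeletal muscle transcripts (-2.53). The low end of that range is out of proportion to the standard error and is not read as support. Dio2 did not pass (-1.73 ± 0.54, adjusted p = 0.051), but did without WT room temperature replicate 1 (-2.37, adjusted p = 8.6e-06), with library totals alone (-1.57, adjusted p = 0.039), without or with a strict filter, with DESeq2 and with limma voom, within a range of 4.4e-22 to 0.18. Further negative differences were found for Acot5 (-3.41 ± 0.76, or -5.02 without WT room temperature replicate 1 and -4.48 with limma voom), Lclat1, an acyltransferase of cardiolipin and other phospholipids (-2.97 ± 0.39), Hpx (-2.82 ± 0.37), the creatine kinase Ckb (-1.86 ± 0.27), the phosphatase Alpl (-1.37 ± 0.23) and Manf, a protein of endoplasmic reticulum stress (-1.44 ± 0.12). Positive ones were found for Cfap53 (3.2 ± 0.4), the kinase Map2k6 (2.84 ± 0.36), Dgat2 (1.18 ± 0.22) and Acat3 (2.63 ± 0.63, or 3.28 without WT cold replicate 2), which is antisense to Tcp1 and whose call ended without the libraries richest in skeletal muscle transcripts (2.37, adjusted p = 0.055, within 4.5e-13 to 0.055 over its alternatives).

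The heat shock list differed between the genotypes in its cold response, with 8 of 11 genes negative and 0 positive, or 9 and 0 adjusted over the list alone, including Hsp90ab1 (-1.52 ± 0.14) and Hsp90aa1 (-1.59 ± 0.21). Its median difference was -1.02 (adjusted p = 4.8e-14, and adjusted p = 0.1 with an estimated correlation). The thermogenic list had 7 of 17 genes negative and 0 positive, or 10 and 0 adjusted over the list alone, with the potassium channel Kcnk3 at -1.12 ± 0.23. The thermogenic median difference was -0.68 (adjusted p = 0.00046, and adjusted p = 0.11 with an estimated correlation). The glycolysis list had 8 of 17 genes negative and 0 positive, also adjusted over the list alone, with Pfkp at -0.9 ± 0.14 and Hk1 at -1.02 ± 0.16. The glycolysis median difference was -0.4 (adjusted p = 0.00092, and adjusted p = 0.52 with an estimated correlation). With library totals alone 2 glycolysis genes were negative and the median was -0.17. The interferon list had 2 of 16 genes positive, or 6 adjusted over the list alone, with Ifit2 at 1.09 ± 0.22. For interferon genes the median difference was 0.64 (adjusted p = 0.0038, and adjusted p = 0.88 with an estimated correlation). Under library totals alone the medians were -0.79 for heat shock, -0.46 for thermogenic and 0.86 for interferon genes. The interaction was past the test for 3581 genes, 1614 positive and 1967 negative, or 2388 and 711 with library totals alone, where the median of all genes went from 0.01 to 0.24, and for 1903 genes without the libraries richest in skeletal muscle transcripts. Of the 3581 genes, 1681 rose in WT with a negative difference and 1405 fell in WT with a positive difference. The WT cold response enters the difference with the opposite sign, so these opposite signs are in part built in and are no separate evidence. The number of lists was 4, or 7 without WT cold replicate 1 and 0 with an estimated correlation.

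**Figure D2:**
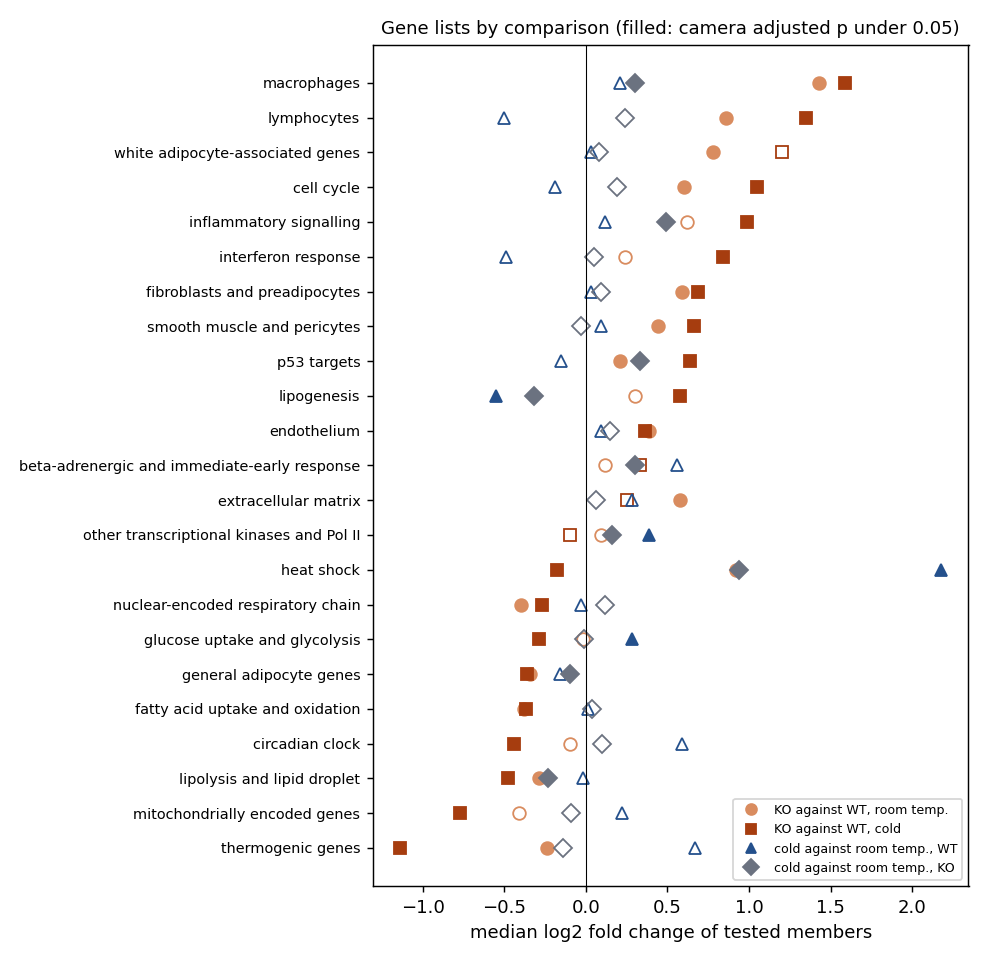
Median log2 fold change (horizontal axis) of the 23 gene lists that passed in at least 1 comparison, with a marker shape for each of the 4 pairwise comparisons and filled markers where the camera adjusted p was under 0.05. The heat shock median was 2.18 for cold in WT and 0.94 for cold in KO. With library totals alone the medians for KO against WT in the cold turn to positive for fatty acid uptake and oxidation (0.07), respiratory chain (0.17), glycolysis (0.15), heat shock (0.26) and general adipocyte genes (0.07), and to 0 for circadian genes.

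Over the 7034 genes called in WT, the median ratio of the cold log2 fold change in KO to that in WT was 0.24, with quartiles of -0.0121 and 0.507, and 73.9% had the same sign. Over the 1479 genes called in both genotypes it was 0.696, and over the 2258 called in KO it was 0.769, so the ratio depends on where the genes are chosen. Genes that rose in the cold in both genotypes numbered 721 where independent lists would share 255, genes that fell in both 632 against 267, and opposite calls 126 against 522. Across all tested genes, which are not independent replicates, cold responses of the genotypes had a Pearson correlation of 0.486. Genotype differences at both temperatures had one of 0.607, or 0.257 with no filter beyond 1 count. In the main fit 1795 genes were higher in KO at both (761 for independent lists), 1837 lower at both (888) and 431 opposite (1645).

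**Figure D3:**
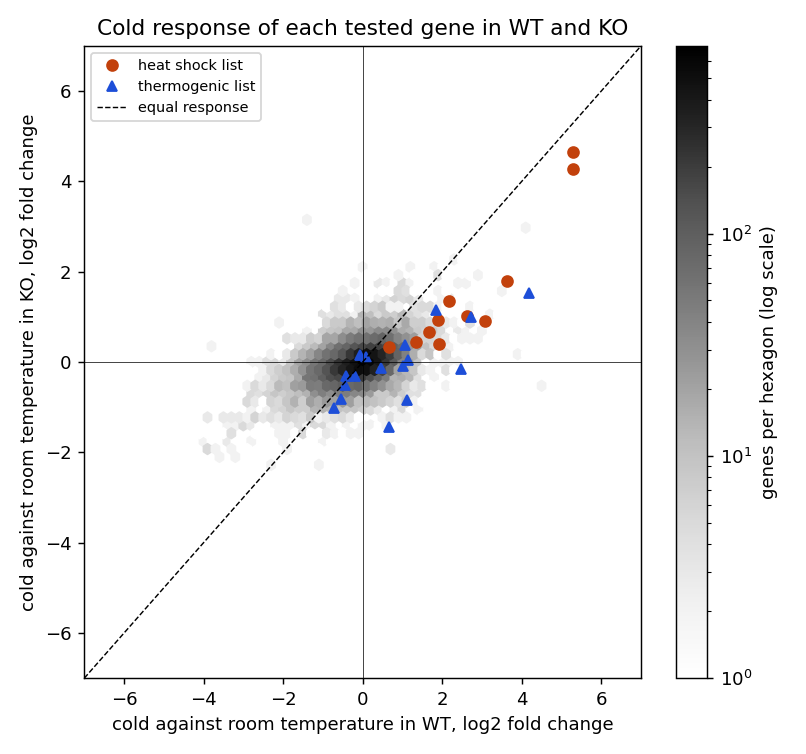
Log2 fold change of cold against room temperature in WT (horizontal axis) and in KO (vertical axis) for the 15208 tested genes, shaded by gene density on a log scale, with heat shock genes as circles, thermogenic genes as triangles and a dashed line of equal response. Across genes the correlation was 0.486, and Ucp1 was at 1.14 in WT and 0.04 in KO.

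KO at room temperature was also set against the cold response of WT. Genes higher in KO that also rose in WT in the cold numbered 1008 (677 for independent lists), genes lower in KO that also fell 1521 (743), and opposite calls 619 (1419). Both comparisons use the same WT room temperature libraries, which adds covariance by chance. The covariance of the log2 fold changes across genes was 0.218, while 20 simulations of unchanged groups against those libraries gave a mean of 0.0523 and at most 0.0575, so that the difference was 0.166. The Pearson correlation was 0.382 against a simulated 0.496. WT at room temperature has too few libraries to split, and part of the excess overlap may come from the shared controls.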

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

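The tests of a generally smaller response and of equal levels reached in the cold were chosen only after the results they bear on had been seen. The fit with the skeletal muscle covariate was added after the data were seen.

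The cold response differed between WT and KO by the test of the difference itself for 3581 of 15208 genes (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 pools per group). Cold raised Ucp1 in WT by 1.14 on the log2 scale and left it at 0.04 in KO, a difference of -1.1. Other genes that rose in WT with a negative difference were Ppargc1a (-2.64), Dgkg (-3.88), Pimreg (-3.51), Acot5 (-3.41, or -5.02 without WT room temperature replicate 1), Hpx (-2.82) and Lclat1 (-2.97). Positive differences were found for Angpt1 (3.21), Hcar1 (2.73) and Acat3 (2.63, or 3.28 without WT cold replicate 2), which fell in WT, and for Cfap53 (3.2) and Map2k6 (2.84). The calls of Ppargc1a and Acat3 ended without the libraries richest in skeletal muscle transcripts. Among the gene lists, medians of the difference were -1.02 for heat shock, -0.68 for thermogenic, -0.4 for glycolysis and 0.64 for interferon response genes, and no list call held with an estimated correlation (smallest adjusted p 0.1).

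Of 60 drawn regroupings of genotype within temperature, 5 called as many genes for the difference in cold response as the real 3581, the real one included, and the highest other called 8681. Chance is not excluded by this count, but the count cannot decide on it either. The regroupings with as many calls exchanged the genotypes of all or most libraries at 1 temperature, so that the contrast added up the genotype differences of both temperatures. Their high counts follow from those differences and do not show what chance gives. The full exchange gave 8681, and 3 of the 14 draws with 1 library per genotype out of place reached at most 3939, while the 44 draws with 2 out of place per genotype called at most 84. For each pairwise comparison the 6 libraries make 10 splits, too few for a share under 0.05. The real split was 1 of the 10 in each. In fits of those 6 libraries alone the real split called 5041 genes for KO against WT at room temperature (highest other 61), 8353 in the cold (1), 6808 for cold in WT (0) and 1993 for cold in KO (0).

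As a list and on the log2 scale, heat shock genes rose less in the cold in KO than in WT. In CPM the inducible Hsp70 genes gained more in KO. Hspa1a went from 1.91 to 48.1 CPM in KO against 0.384 to 15.7 CPM in WT, and Hspa1b from 2.79 to 54.3 CPM against 0.655 to 26.9 CPM. In the cold 5 other members were lower in KO than in WT. If both genotypes reached the same level and KO only started higher, no member would differ in the cold, but 8 of 11 did. A list with no such calls was unlikely in any case, since 53.7% of all tested genes differed between KO and WT in the cold. The 5 members lower in KO (Hspa8, Hsp90aa1, Hsp90ab1, Hspe1 and Hspd1) go against the same level being reached. The 3 higher ones (Hspa1a, Hspa1b and Dnajb1) were above WT in every KO pool at room temperature too, so they do not go against a higher start. The other 3 (Hsph1, Hspb1 and Bag3) were higher in KO at room temperature, and for these few genes a higher start cannot be told apart from other causes. Skeletal muscle RNA is argued against as the whole cause, since the median difference was -0.98 with the muscle covariate. A smaller cold response over genes in general stays open as a candidate explanation, because the choice of reference genes decides the comparison. The median ratio of KO to WT responses over the heat shock genes was 0.494 (members 0.211 to 0.878). It was not below the 0.24 over all genes called in WT or the 0.262 over the 1777 of them changed by at least 2-fold. But all 11 heat shock genes were called in both genotypes, and over the 1479 genes called in both the median ratio was 0.696, above 0.494.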

How the results depend on the processing

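The fits with library totals alone, with the muscle covariate and without the libraries richest in skeletal muscle transcripts were chosen only after the data had been seen, as were the alternatives for the relations between comparisons. Of 299 results for named genes, 245 kept their direction and side of the threshold under every alternative tried and 292 were never reversed. Of 51 list calls 3 kept theirs under all alternatives, since all others ended with an estimated correlation. None was reversed in the direction of its test, though 5 medians turned with library totals alone. Of 14 values for whole comparisons 4 moved under no alternative. Library totals alone moved the medians of all genes because TMM factors were 0.798 to 0.87 in WT cold libraries and 1.07 to 1.18 in KO libraries, and whether the shift reflects total RNA per cell cannot be read from these data. At 27609717 counts or more per library, depth limits genes such as Car6 in WT (0.134 CPM), whose fold change rests on few counts.

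Values of uncalled genes changed sign around 0, as did those of Atp5b and Sdha, which had been called. The difference in cold response of Cdk7 was 0.02 with no filter, 0 with the strict filter, 0.19 with library totals alone and 0.11 without the libraries richest in skeletal muscle transcripts. With library totals alone Cdk7 was at -0.13 for cold in WT, and KO against WT in the cold turned to 0.01 for Atp5b and 0.04 for Sdha, whose calls ended because the fold changes of that comparison moved up with the median of all genes, which was then 0.45. With limma voom Cdk7 was at -0.09 for cold in KO. Without the muscle-rich libraries cold in KO gave -0.03 for Ucp1 and 0.05 for Ppargc1a.

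Genes changed by cold in KO numbered 1476 with library totals alone, 1214 without the muscle-rich libraries and 4092 with limma voom. Without the muscle-rich libraries, and so with fewer samples, 3566 genes changed for KO against WT at room temperature and 1903 differed in cold response. Lists changed by cold in WT numbered 10 with no filter and 8 with library totals alone, and 8 lists differed in cold response with no filter. With an estimated correlation 0 lists changed for KO against WT at room temperature, 1 for KO against WT in the cold, 1 for cold in WT, 1 for cold in KO and 0 for the difference. The correlation of genotype differences at both temperatures was 0.257 with no filter, 0.508 without the muscle-rich libraries and 0.554 with limma voom. The ratio of cold responses was 0.769 over genes called in KO, which selects genes with larger values there. Except where stated, the cause was not tested.

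With each library left out in turn, genes changed by cold in KO ran from 1171 to 2538, lists from 5 to 11 for cold in KO, 4 to 8 for cold in WT and 4 to 7 for the difference, the correlation from 0.451 to 0.627 and the ratio from 0.181 to 0.3. Cdk7 ran from -0.07 to 0.14 for cold in KO and from -0.13 to 0.07 for the difference, Ppargc1a from -0.33 to 0.05 and Ucp1 from -0.03 to 0.12 for cold in KO.

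Replicate numbers showed no sign of pairing the samples: of 9 same-numbered pairs of samples 1 had a correlation of deviations over 0.1 (range -0.31 to 0.23), and in 2 of the 9 a sample correlated best with its own number. With so few pools per group this cannot exclude a pairing, and KO at room temperature, numbered otherwise, was not in the check. With the replicate block 7691 genes changed for KO against WT in the cold and 6671 for cold in WT, and the calls of Ppargc1a (adjusted p = 0.085) and of the mitochondrially encoded list (0.088) for KO against WT in the cold ended, while no other named call changed.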

Other observations

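The tests of macrophage against endothelial markers, of other markers against those of erythrocytes, of marker levels per library and of the range of medians in the cold were chosen only after their results had been seen, as were the 19 gene families, which were examined over 5 comparisons (95 list tests adjusted together), and the fits with library totals alone and with the muscle covariate. None of the families passed with an estimated correlation.

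Histone genes were higher in KO. Of 23 tested histone genes, 16 rose and 1 fell at room temperature (median log2 fold change 1.71, adjusted p = 8.3e-08, and adjusted p = 0.21 with an estimated correlation) and 18 rose and 0 fell in the cold (1.91, adjusted p = 6.1e-08, and adjusted p = 0.21 with an estimated correlation), with medians of 1.92 and 2.35 under library totals alone. Their median for cold in WT was -0.19 (adjusted p = 0.72). Hist1h4h, an example chosen after its values were seen, was at 2.39 at room temperature and 2.2 in the cold. Tubulin genes rose in 8 of 13 cases and fell in 0 in KO at room temperature (median 0.49, or 0.69 with library totals alone, adjusted p = 0.00086, and adjusted p = 0.25 with an estimated correlation). In the cold 6 tubulin genes were higher and 3 lower in KO (median 0.33, adjusted p = 0.78), and the difference in cold response had a median of -0.65 (adjusted p = 0.0035, and adjusted p = 0.25 with an estimated correlation).

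In WT, cold raised genes of protein folding and turnover beyond the heat shock list. Of 37 proteasome genes 23 rose and 3 fell (median 0.43, or 0.23 with library totals alone, adjusted p = 2.5e-05, and adjusted p = 0.35 with an estimated correlation). Of 7 genes of the CCT chaperonin, which folds actin and tubulin, 6 rose and 1 fell (median 0.65, or 0.46 with library totals alone, adjusted p = 0.00012, and adjusted p = 0.25 with an estimated correlation). By the test of the difference in cold response, 12 proteasome genes were negative and 1 positive (median -0.25, adjusted p = 0.001, and adjusted p = 0.48 with an estimated correlation) and 6 CCT genes negative and 0 positive (median -0.49, adjusted p = 0.0015, and adjusted p = 0.34 with an estimated correlation). Under library totals alone 4 proteasome genes were negative and 3 positive (median -0.02), so no direction is given for that family, and 2 CCT genes were negative and 0 positive (median -0.26). Of 17 aminoacyl-tRNA synthetase genes 12 rose and 4 fell in WT in the cold (median 0.48, or 0.29 with library totals alone, adjusted p = 0.0054, and adjusted p = 0.39 with an estimated correlation).

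Markers of macrophages, endothelium, fibroblasts and smooth muscle were higher in KO than in WT, as were those of lymphocytes (median 0.86, adjusted p = 0.03) and, without passing as a list, of Schwann cells and nerve (0.7, adjusted p = 0.15), with no such list past the test at an estimated correlation (smallest adjusted p 0.11), while 0 of 6 erythrocyte genes (-0.12) and 0 of 15 skeletal muscle genes (-0.01) passed at room temperature, and in the cold 1 erythrocyte gene was higher (0.25, or 6 of 6 at 0.7 with library totals alone) and skeletal muscle genes were at 1.71 with 0 past the test. A lower share of adipocyte RNA would raise the markers of all other cells alike. It is argued against as the whole cause for macrophages, whose mean level per library rose over that of the endothelium by 1.14 (2-sided exact permutation p = 0.005 with genotype exchanged within temperature, the smallest it can give). The macrophage median exceeded that of the endothelium by 1.04 at room temperature (2-sided permutation p over genes = 0.011) and by 1.23 in the cold (permutation p = 0.0017). Permutations over genes treat co-regulated markers as independent and do not measure the spread between pools. The endothelium median (0.39 and 0.36) was below those of fibroblasts (0.59 and 0.69) and smooth muscle (0.44 and 0.66) at both temperatures, which enlarges the excess. For the endothelium, fibroblast and smooth muscle lists the test planned for room temperature met what a lower share predicts. Their medians were all above 0, with a range that had a permutation p over genes of 0.61. But their mean level per library rose over that of the erythrocyte genes by 0.52 there, with every KO library above every WT library, and by 0.24 in the cold. The 2-sided exact permutation p was 0.015 for both temperatures together. A lower share alone would not give this difference unless the blood in the tissue changed as well. The libraries at room temperature alone are too few for a p under 0.05. With the planned test pointing the other way, a lower share stays open for these lists at room temperature. In the cold a lower share cannot be told apart from other causes for these lists. KO and WT libraries overlapped there in the difference from erythrocyte genes, and the range of medians had a permutation p of 0.038, or 0.051 adjusted over 4 tests over genes. Scaling moves all genes of a comparison alike, so the excess of the macrophage median over that of all genes, 1.42 with library totals alone, is no test of it, and more macrophages, or more transcripts of these genes per macrophage, stay open as untested candidate explanations.

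KO at room temperature differed from WT in the direction of the WT cold response. The covariance of the fold changes was 0.218, or 0.23 with the muscle covariate, against at most 0.0575 in simulations of unchanged groups. That argues against the shared WT libraries, and against skeletal muscle RNA, as the whole cause only as far as the simulations hold. They drew all 12 libraries anew, so the deviations of the real WT libraries are not in them, and drew genes independently with 1 dispersion per gene for all groups. Pools of WT at room temperature differed most, with a chi-square of up to 99 per degree of freedom, so the simulated maximum may be too low. The Pearson correlation was 0.382, below the simulated 0.496, but changes of either comparison alone lower it, so it does not measure what the shared libraries add. A partial cold-like state of KO stays open as an untested candidate explanation: heat shock genes had medians of 0.92 in KO at room temperature and 2.18 for cold in WT, but lipogenesis genes had 0.3 and -0.55, and Ucp1 was at -0.88 and 1.14.

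Of 13 mitochondrially encoded protein genes 6 had fewer than 100 counts in every library, at most 47, while each of the others had at least 4383. Without TMM factors the mitochondrial ribosomal RNAs had 2173 to 3715 CPM (mt-Rnr1) and 4604 to 9401 CPM (mt-Rnr2) in the libraries at room temperature, and 6976 to 10048 and 15363 to 25421 CPM in those in the cold.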
